A study of Mus musculus with 40 samples.

How the data were processed

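RNA was measured in 40 libraries of mouse bone marrow cells, made from polyA RNA that was reverse transcribed and amplified with a modified SMART-Seq2 protocol, per the labels' protocols. The libraries cover long-term haematopoietic stem cells (LT-HSC, 4 Dnmt3a knockout and 4 wild-type), short-term haematopoietic stem cells (ST-HSC, 4 and 4), common and granulocyte-macrophage progenitors (CMP/GMP, 4 and 4), megakaryocyte-erythroid progenitors (MEP, 4 and 3) and c-kit+ cells (2 wild-type, 2 Dnmt3a knockout, 2 Sting knockout and 3 double knockout). Groups were taken from the labels alone.

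The submitters deposited raw read counts per gene symbol and raw read counts per subfamily of transposable elements (TE). Reads were trimmed with Trim Galore 0.6.7, aligned to mm10 with HISAT2 and assigned with featureCounts 2.0.1, and DESeq2 1.34.0 was used, per the submitters' processing notes. The annotation, the strand setting, the treatment of reads that map to several places and the way reads were assigned to TE subfamilies are not given in the sources used here. Reads of a gene and of an overlapping or antisense partner can therefore not be told apart, and genes with near-identical copies are called uncertain where they are named. The gene table holds 35976 symbols, of which 32501 matched a symbol of the GRCm38.p6 gene table and 1005 more matched through an older symbol, and positions are those of that assembly. Of its 40 columns, 32 could be matched to a single library. The other 8 were not used, because they repeat the names of the ST-HSC wild-type libraries and none is named for the ST-HSC knockout. No gene-level comparison of ST-HSC was therefore run, and the interferon list was not tested there. The TE table holds 1146 subfamilies, and its 40 columns were all used.

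Counts were analysed in R 4.3.3. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 after TMM normalization, with a filter on low counts (filterByExpr, minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Each sorted population was fitted alone. The 9 c-kit+ libraries were fitted together, so that groups of 2 and 3 libraries share an estimate of the spread, and the interaction contrast took the effect of Dnmt3a loss without Sting minus its effect with Sting. The difference of the Dnmt3a effect between populations was tested with an F-test over LT-HSC, CMP/GMP and MEP. ST-HSC had been planned as a further population of that test and was left out with its gene columns. TE subfamilies were tested in the same way with library sizes and TMM factors of the gene counts, except in ST-HSC, where those of the TE counts themselves were used because no gene total could be assigned. TE reads per 100 gene reads were compared by two-sided exact permutation tests, adjusted over the comparisons of each measure.

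The tests, the 22 gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The lists cover interferon-stimulated genes, nucleic acid sensing, NF-kB and inflammatory genes, MHC class I, haematopoietic stem cell genes, lymphoid priming, granulocytic, monocytic, erythroid, megakaryocytic, B cell, T and NK cell, basophil, mast cell and eosinophil, and stromal and endothelial genes, G1/S, G2/M, p53 targets, germline genes, imprinted genes, the methylation machinery, TE silencing and handling stress. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. Lists with fewer than 3 tested members were left out, which applied to the B cell list in LT-HSC and MEP and to the germline list in all 3 sorted populations with gene counts. Genes were named by a fixed rule. Dnmt3a and Tmem173, the gene of Sting, are always named. Up to 8 rises and 8 falls per contrast are named among called genes with a mean of at least 5 CPM (reads scaled to library size), groups that do not overlap and a symbol that is not a predicted-gene name. Up to 3 called members of each list, the 2 most abundant members of lists without a called member, as values, and up to 5 TE subfamilies per direction are named too. A gene that this rule picks is not reported here. Other genes named are said to have been chosen after their values were seen.

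Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no filter on low counts, the replicate number as a block, only the 2 groups compared, 1 fit over the sorted populations, TE library sizes, other TE denominators and classes, and leaving out each library in turn. A term for the sex of each library, tests without genes of chromosomes X and Y, a block of genotype and number over the sorted populations, and libraries summed or left out as pairs were added after seeing the data. The planned test of genes called in several sorted populations, and the overlap of calls between populations, had no called genes to use. In place of the first, genes called in c-kit+ cells were tested as lists in the sorted populations, chosen after seeing the data.

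Simulated data with known fold changes were used to test the gene fits of Dnmt3a KO against WT in each population, of DKO against Dnmt3a KO and against Sting KO and of the c-kit+ interaction, the TE fits of Dnmt3a KO against WT, camera on 1 planted list and the exact permutation test. The interaction between populations, Sting KO against WT and DKO against WT were not simulated in this way, nor were the other TE contrasts of c-kit+ cells. For Dnmt3a KO against WT in c-kit+ cells (16026 genes), edgeR recovered 46.3% of genes changed 2-fold, 79.1% changed 4-fold and 92.4% changed 8-fold, with 14 false calls. The shares were 23.9%, 59.7% and 63.6% in CMP/GMP (13205 genes), 0%, 25.4% and 48.5% in LT-HSC (12800 genes) and 0%, 2.99% and 33.3% in MEP (12323 genes). For the c-kit+ interaction they were 31.3%, 59.7% and 75.8%. TE recovery (of 4-fold changes) was 98.5% in c-kit+ cells, 40.3% in LT-HSC, 64.2% in ST-HSC, 85.1% in CMP/GMP and 23.9% in MEP. For Dnmt3a KO against WT, edgeR made 3, 6 and 3 false calls in LT-HSC, CMP/GMP and MEP. On the same simulated data DESeq2 recovered more changed genes but made 60, 45 and 60 false calls there, and 34 in c-kit+ cells. Voom made 0, 5 and 0 false calls in LT-HSC, CMP/GMP and MEP, and 14 in c-kit+ cells. Correlations between contrasts that share libraries were set beside 20 simulated draws of unchanged groups. Counting intervals are Wilson intervals at 95%, and a count of 0 is given with the upper limit that 3 reads set.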

Results

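Gene expression was measured in bone marrow cells of mice with loss of Dnmt3a, a DNA methyltransferase often mutated in clonal haematopoiesis, of Sting, the adaptor through which cytosolic DNA induces interferon, or of both. Sorted LT-HSC, ST-HSC, CMP/GMP and MEP compare Dnmt3a knockout (KO) with wild-type (WT) cells, with 4 libraries in each group except 3 of MEP WT. The c-kit+ cells, a mixed progenitor fraction, add a Sting KO and a Dnmt3a/Sting double knockout (DKO), with 2 WT, 2 Dnmt3a KO, 2 Sting KO and 3 DKO libraries. The Dnmt3a KO was made with Mx1-Cre, a recombinase under an interferon-inducible promoter. How it was induced and whether WT animals carried it are not given in the sources used here. Reads assigned to genes, in M (1e6 reads), ranged from 27.4 to 40.0 M in c-kit+, 33.2 to 47.7 M in CMP/GMP, 16.9 to 45.8 M in LT-HSC and 3.44 to 36.0 M in MEP. Reads assigned to transposable elements (TE) ranged from 1.02 to 1.28 M in c-kit+, 0.895 to 1.86 M in CMP/GMP, 1.31 to 2.98 M in LT-HSC, 0.392 to 2.63 M in MEP and 0.840 to 3.64 M in ST-HSC. Levels of single libraries are CPM, the reads of a gene scaled to all gene reads of the library. Group levels are mean ± SD of CPM after TMM normalization, with n libraries. Errors of log2 fold changes are standard errors (SE). Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera. The labels name no animals, so all p-values measure only the spread between these libraries. Intervals and limits for a count of 0 cover counting error only. Positions are chromosome, start and end in GRCm38 (mm10).

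Dnmt3a (12: 3801559 to 3914443) and Tmem173, the gene of Sting (18: 35733678 to 35740554), were first read in every library. In c-kit+ cells Dnmt3a was at 91.1 and 79.9 CPM in WT and 77.4 and 96.8 CPM in Sting KO. It was at 48.3 and 48.9 CPM in Dnmt3a KO and 41.8, 48.1 and 50.8 CPM in DKO. Tmem173 was at 55.4 and 65.1 CPM in WT and 43.8 and 47.4 CPM in Dnmt3a KO. It was at 10.2 and 9.61 CPM in Sting KO and 10.4, 9.91 and 11.7 CPM in DKO. Every c-kit+ library thus lay on the side of its label for both genes, with transcript left in each knockout. Which part of either transcript the alleles remove is not given in the sources used here. In CMP/GMP Dnmt3a was at 15.8, 16.9, 33.5 and 33.4 CPM in KO and 55.7, 66.6, 49.8 and 83.0 CPM in WT. In LT-HSC it was at 41.7, 71.6, 119 and 50.8 CPM in KO and 230, 77.2, 109 and 104 CPM in WT. The library labelled LT-HSC Dnmt3a KO 3 thus lay above 3 of the 4 WT libraries. In MEP it was at 10.8, 41.9, 1.64 and 1.16 CPM in KO and 49.5, 32.1 and 29.4 CPM in WT. The library labelled MEP Dnmt3a KO 2 thus lay above 2 of the 3 WT libraries. The Wilson intervals at 95% were 1.21 to 2.24 CPM for MEP Dnmt3a KO 3 (40 reads) and 0.81 to 1.65 CPM for MEP Dnmt3a KO 4 (30 reads). ST-HSC libraries could not be checked in this way, since their gene columns were not used here. In c-kit+ cells Xist, the RNA of the inactive X chromosome, was at 1810 to 2307 CPM in both Dnmt3a KO libraries and DKO 1. The WT, Sting KO and other DKO libraries had transcripts of the Y chromosome.

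**Figure D1:**
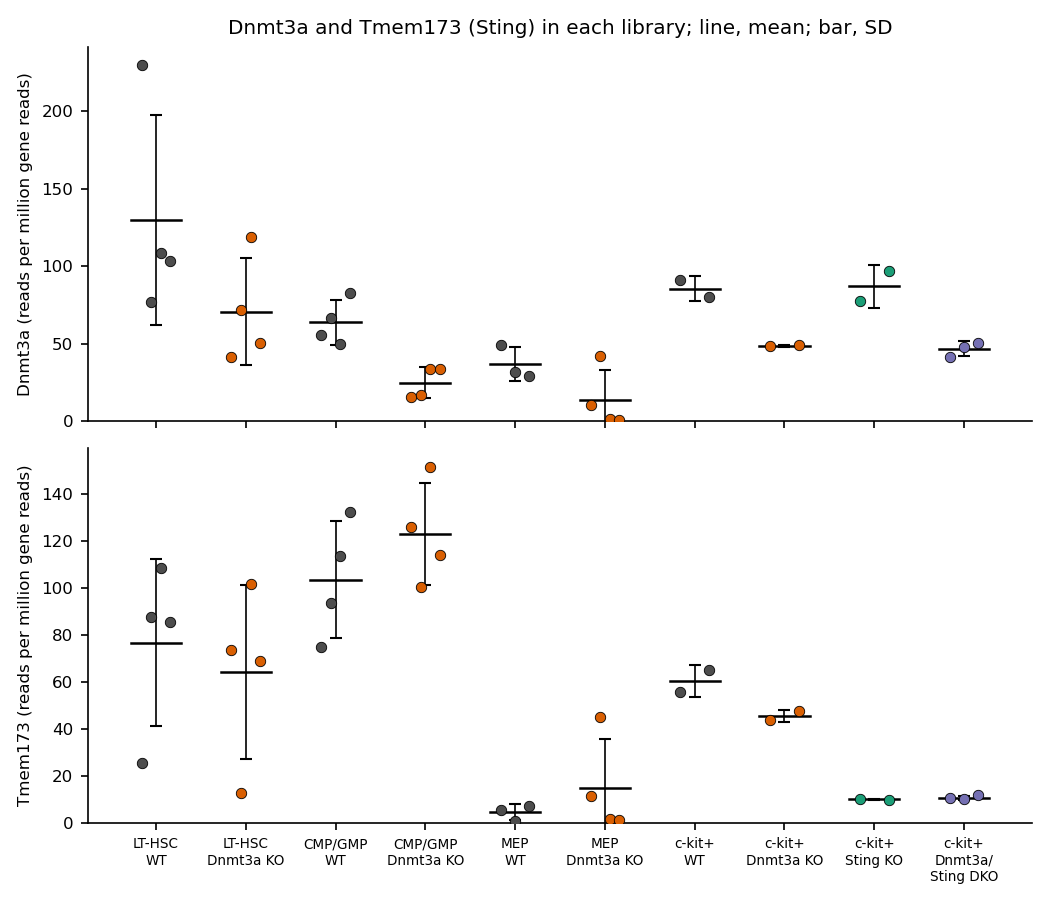
Dnmt3a and Tmem173 in every library with gene counts, in CPM, 1 point per library, grouped by cell population and genotype, with group means and SD. In c-kit+ cells Tmem173 lies between 9.61 and 11.7 CPM in the 5 libraries without Sting, and between 43.8 and 65.1 CPM in the other 4.

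The comparison of Dnmt3a KO with WT in c-kit+ cells asks what loss of Dnmt3a changes while Sting is present. Fold changes were positive for 42 of the 44 measured interferon-stimulated genes, and 10 genes of this list were called higher. Oas3 (5: 120753098 to 120777684), a 2'-5' oligoadenylate synthetase that senses double-stranded RNA, was at 39.4 ± 1.27 CPM in Dnmt3a KO and 7.48 ± 0.620 CPM in WT (n = 2 each; log2 fold change 2.40, SE 0.260, adjusted p = 0.00685, edgeR). Ddx58 (4: 40203777 to 40239825), the RNA sensor RIG-I, was at 57.4 ± 4.44 and 29.8 ± 1.53 CPM (log2 0.95, SE 0.105, adjusted p = 0.00685, edgeR). Oas2 (5: 120730333 to 120749886) rose by 2.49 on the log2 scale (SE 0.358, adjusted p = 0.0186) and Oas1a (5: 120896256 to 120907544) by 1.69 (SE 0.225, adjusted p = 0.0150). The Oas genes are close copies of each other in 1 cluster, so how reads were shared among them is uncertain. In the list 34 genes did not pass, none fell, and 29 rose when adjusted over the list alone. The list's median log2 fold change was 0.82 (adjusted p = 5.14e-18, camera, and 0.673 with an estimated correlation). Isg15, the list's remaining gene, reached at most 0.120 CPM in any library and was not tested. Both Dnmt3a KO libraries are the Xist libraries of this comparison, and with a term for sex, chosen after seeing the data, the median was 0.54. In c-kit+ cells that term is set by DKO 1 against DKO 2 and DKO 3, since only DKO held both Xist and Y libraries.

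Among other called genes, Prg2 (2: 84980461 to 84983632), the major basic protein of eosinophil granules, was at 1011 ± 192 CPM in Dnmt3a KO and 2810 ± 105 CPM in WT (n = 2 each; log2 -1.48, SE 0.166, adjusted p = 0.00685, edgeR), and Epx (11: 87863997 to 87875536), eosinophil peroxidase, at 428 ± 137 and 1061 ± 128 CPM (adjusted p = 0.0392). Hmox1 (8: 75093618 to 75100593), the haem oxygenase of macrophages that clear red cells, was at 68.4 ± 4.99 and 346 ± 52.5 CPM (log2 -2.34, SE 0.308, adjusted p = 0.0144, edgeR). Cd68 (11: 69664213 to 69666170), a lysosomal protein of macrophages, fell by 0.91 on the log2 scale (adjusted p = 0.0334). Col1a2 (6: 4505618 to 4541543), a collagen chain, fell by 1.96 (adjusted p = 0.0279). Falls were seen too in Gpr137b (13: 13357620 to 13393644), a lysosomal membrane protein, by 2.42, the kinase gene Dmpk (7: 19083646 to 19093821) by 2.33, the adhesion molecule Cadm1 (9: 47530170 to 47862280) by 2.03 and the phospholipase gene Gdpd3 (7: 126766414 to 126775645) by 1.98, with adjusted p from 0.0181 to 0.0488. Ncr1 (7: 4337715 to 4345184), an activating receptor of NK cells, rose from 1.88 ± 0.0352 to 5.90 ± 0.717 CPM (adjusted p = 0.0334). Other rises were Chil3 (3: 106147554 to 106167564), a chitinase-like protein of myeloid cells (1621 ± 88.4 against 150 ± 81.8 CPM, adjusted p = 0.0209), and Gdf3 (6: 122605403 to 122610087), a growth factor of the TGF-beta family (adjusted p = 0.0334). So did Apobec3 (15: 79892058 to 79918218), a cytidine deaminase that restricts retroviruses (224 ± 13.1 against 67.9 ± 0.833 CPM, adjusted p = 0.000779), Rps4l (6: 148354656 to 148355596), a copy of a ribosomal protein gene (adjusted p = 0.00871), and Pnp2 (14: 50956141 to 50964751), a purine nucleoside phosphorylase. Pnp2 was at 14.01 ± 0.0171 CPM in Dnmt3a KO and 0.367 ± 0.253 CPM in WT (log2 5.19, SE 0.370, adjusted p = 0.000779, edgeR). Chil3, Apobec3, Rps4l and Pnp2 have near-identical copies or overlapping genes, so their counts are uncertain. Ccnb1ip1 (14: 50789249 to 50795728), a protein of meiotic crossing over, was at 15.3 CPM (Wilson interval 13.9 to 16.7) and 20.4 CPM (19.1 to 21.9) in WT, with 0 to 2 reads in each mutant library of all 3 genotypes. Apobec3, Chil3, Pnp2, Rps4l, Ccnb1ip1, Hmox1, Cd68, Dmpk, Cadm1 and Gdpd3 were called on the same side of WT in Sting KO and DKO too. Prg2 and Gpr137b also fell in Sting KO, where Dnmt3a was not lost.

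Other lists shifted too in Dnmt3a KO against WT by camera. Lower were stromal and endothelial genes (1 of 11 fell, 7 adjusted over the list alone, adjusted p = 7.52e-05), basophil, mast cell and eosinophil genes (2 of 9 fell, 4 adjusted over the list alone, 0.00550) and monocytic genes (2 of 15 fell, with 1 higher and 5 lower adjusted over the list alone, 0.0135). Also lower were handling stress (0 of 14 called, though none had a positive fold change, 0.0127), lymphoid priming (0 of 10, 3 lower adjusted over the list alone, 0.0167), NF-kB and inflammatory genes (0 of 23, 1 lower, 0.0276) and B cell genes (0 of 12, 2 lower, 0.0371). The megakaryocytic (0 of 17 changed, adjusted p = 0.00874), granulocytic (0 of 16, 0.0119), G2/M (0 of 17, 2 higher adjusted over the list alone, 0.0371) and stem cell lists (0 of 25, 3 higher, 0.0399) shifted up. For all of them camera gave adjusted p = 0.673 with an estimated correlation. The lists of nucleic acid sensing (0.950), MHC class I (0.719), erythroid genes (0.719), T and NK cells (0.900, with Ncr1 higher), G1/S (0.734), p53 targets (0.0907), germline genes (0.554), imprinted genes (0.950), the methylation machinery (0.719) and TE silencing (0.182) did not pass in camera. Median, mean and test differed in sign for nucleic acid sensing, erythroid, imprinted and methylation genes.

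In all, edgeR called 91 of 16026 genes, 49 higher and 42 lower in Dnmt3a KO than in WT, where DESeq2 called 645 and voom with quality weights 924. Dnmt3a itself fell by 0.81 on the log2 scale (SE 0.131, adjusted p = 0.0320, edgeR), from 84.1 ± 7.02 to 47.9 ± 0.159 CPM, and Tmem173 had a log2 fold change of -0.40 (adjusted p = 0.151). With libraries left out, genes changed in c-kit+ Dnmt3a KO against WT numbered 8 without Dnmt3a KO 1, 10 without Dnmt3a KO 2, 6 without WT 1, 11 without WT 2, 289 without DKO 2 and 266 without DKO 3, and 0 with the term for sex. A lone library was there assumed to vary like the other groups. The call of Dnmt3a in c-kit+ Dnmt3a KO against WT was lost without Dnmt3a KO 1 (log2 -0.83), Dnmt3a KO 2 (-0.82), WT 1 (-0.74) and WT 2 (-0.90).

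Sting KO against WT in c-kit+ cells asks what loss of Sting changes while Dnmt3a is present. Tmem173 fell from 59.3 ± 7.24 CPM in WT to 10.02 ± 0.424 CPM in Sting KO (n = 2 each; log2 -2.57, SE 0.125, adjusted p = 4.2e-05, edgeR), while Dnmt3a had a log2 fold change of 0.07 (adjusted p = 0.884). Mrc1 (2: 14229414 to 14332023), the mannose receptor, was at 23.8 ± 0.0692 against 179 ± 13.01 CPM (log2 -2.91, SE 0.542, adjusted p = 0.0478, edgeR). Adgre1 (17: 57358581 to 57483529), the macrophage marker F4/80, was at 11.1 ± 0.331 against 47.4 ± 2.61 CPM (log2 -2.10, SE 0.271, adjusted p = 0.00972) and Hmox1 at 49.0 ± 8.82 against 346 ± 52.5 CPM (log2 -2.82, adjusted p = 0.00549). Cd68 fell by 1.30 on the log2 scale (adjusted p = 0.00617). Ccr3 (9: 124017825 to 124031692), the eotaxin receptor of eosinophils, fell by 2.996 (adjusted p = 0.0334) and Prg2 by 1.22 (adjusted p = 0.0111). The other large falls were in Gpr137b (by 3.402), Kcnj10 (1: 172341210 to 172374085), a potassium channel (by 3.17), Cadm1 (by 3.12) and Rims3 (4: 120854779 to 120896580), a synaptic protein (by 2.76), with adjusted p from 0.00432 to 0.0390. Psmb5 (14: 54614120 to 54617995), a catalytic subunit of the proteasome, rose from 22.1 ± 3.61 CPM in WT (log2 1.26, SE 0.142, adjusted p = 0.00549), and the neighbouring cadherin gene Cdh24 (14: 54631231 to 54642067) rose by 1.15 (adjusted p = 0.0236). Ero1lb (13: 12565818 to 12609533), an oxidase of the endoplasmic reticulum, rose by 1.31 and Hist1h4i (13: 22040960 to 22041362), a histone H4 gene with near-identical copies and therefore uncertain, by 1.56 (adjusted p = 0.0249 and 0.0223). Pnp2, Apobec3 and Chil3 rose as in Dnmt3a KO, by 5.21, 1.74 and 2.62 on the log2 scale (adjusted p = 0.000340, 0.000340 and 0.0478). LOC108168162, for which the gene table gives no position, was at 14.2 ± 1.82 CPM in Sting KO and 0.149 ± 0.210 CPM in WT.

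None of the 44 interferon genes passed in Sting KO against WT, also when adjusted over the list alone, and as a list they were lower, with a median log2 fold change of -0.17 (adjusted p = 0.0186, camera; 0.679 with an estimated correlation). The monocytic list shifted down with 3 of 15 genes lower and 6 adjusted over the list alone (adjusted p = 0.000973), and the granulocytic list up with 0 of 16 called and 2 adjusted over the list alone (0.000382). B cell (0.00131), erythroid (0.00652) and germline genes (0.0228, 1 lower adjusted over the list alone) shifted down, and G2/M (0.00682) and G1/S genes (0.0186) up, each with no gene called over all genes. All of these had camera adjusted p = 0.679 with an estimated correlation. The other 14 lists did not pass, with adjusted p from 0.136 to 0.979, and median, mean and test differed in sign for MHC class I. By edgeR 124 genes changed, 34 higher and 90 lower (DESeq2 449, voom 249). Counts of genes changed in c-kit+ Sting KO against WT were 74 without Dnmt3a KO 1, 69 without Dnmt3a KO 2, 34 without Sting KO 1, 29 without Sting KO 2, 17 without WT 1, 41 without WT 2, 337 without DKO 2 and 188 without DKO 3.

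DKO against Dnmt3a KO asks what loss of Sting changes once Dnmt3a is lost. Fold changes were negative for all 44 interferon-stimulated genes, and 14 of these genes were called lower. Irf7 (7: 141263183 to 141266499), the transcription factor that amplifies interferon responses, was at 5.00 ± 0.970 CPM in DKO (n = 3) and 26.5 ± 7.78 CPM in Dnmt3a KO (n = 2; log2 -2.41, SE 0.217, adjusted p = 0.00668, edgeR), with 9.05 ± 0.917 CPM in WT. Oas3 was at 8.79 ± 2.78 and 39.4 ± 1.27 CPM (log2 -2.16, SE 0.225, adjusted p = 0.0123), and Lgals3bp (11: 118392747 to 118401959), a secreted glycoprotein, at 65.2 ± 10.1 and 145 ± 7.05 CPM (log2 -1.15, SE 0.120, adjusted p = 0.0123). Oas2 fell by 2.69 and Oas1a by 1.84 on the log2 scale. Rtp4 (16: 23520219 to 23614222), an interferon-induced chaperone of receptors, fell by 2.84, Oasl2 (5: 114896926 to 114912245), an oligoadenylate synthetase-like protein, by 1.86 and Tgtp2 (11: 49057196 to 49064212), an interferon-induced GTPase with a near-identical copy, by 1.81, and adjusted p of these 5 genes ranged from 0.0135 to 0.0276. Adjusted over the list alone 36 of the 44 genes fell. The median was -1.12 (adjusted p = 5.94e-42, camera, and 0.174 with an estimated correlation). The rotation test fry, which asks only whether the list's genes move one way on balance, gave adjusted p = 0.0152. For the interferon list fry gave adjusted p = 0.0911 in Dnmt3a KO against WT and 0.266 in the interaction. The Xist library DKO 1 had a mean interferon log2 level of -0.20 over WT, and DKO 2 and DKO 3, which had Y transcripts, of -0.80 and -0.33.

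The other lists moved less in DKO against Dnmt3a KO. MHC class I (0 of 17 called, 3 lower adjusted over the list alone, adjusted p = 8.74e-05, camera; adjusted p = 0.306 with an estimated correlation), stem cell genes (0 of 25, 8.74e-05; 0.651 estimated) and nucleic acid sensing (1 of 19, which is Tmem173, 2 adjusted over the list alone, 0.0336; 0.306) shifted down, as did erythroid genes (0.0471; 0.778), whose median of -0.21 and mean of 0.02 differ in sign. Basophil, mast cell and eosinophil genes (2 of 9 higher adjusted over the list alone, 0.00123; adjusted p = 0.634 with an estimated correlation), granulocytic genes (0.00556), handling stress (0.00556), NF-kB and inflammatory genes (0.0336) and stromal and endothelial genes (1 higher adjusted over the list alone, 0.0471) shifted up, the last 4 with adjusted p = 0.760 with an estimated correlation. The remaining 12 lists did not pass (adjusted p from 0.113 to 0.845), and imprinted genes differed in sign between median, mean and test. Tmem173 fell by 2.06 on the log2 scale (SE 0.108, adjusted p = 8.5e-05, edgeR) and Dnmt3a had a log2 fold change of -0.01 (adjusted p = 0.991). By edgeR 25 genes changed, none higher and 25 lower, against 95 by DESeq2 (25 higher, 70 lower) and 28 by voom. There were fewer or more genes changed in c-kit+ DKO against Dnmt3a KO when libraries were left out, with 1 without Dnmt3a KO 1, 2 without Dnmt3a KO 2, 74 without DKO 1, 9 without DKO 3, 14 without WT 1 and 1 with the term for sex. The call of Irf7 in c-kit+ DKO against Dnmt3a KO was lost without Dnmt3a KO 1 (log2 -2.06), and that of Oas3 in c-kit+ DKO against Dnmt3a KO without Dnmt3a KO 1 (-2.12) or Dnmt3a KO 2 (-2.18).

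**Figure D2:**
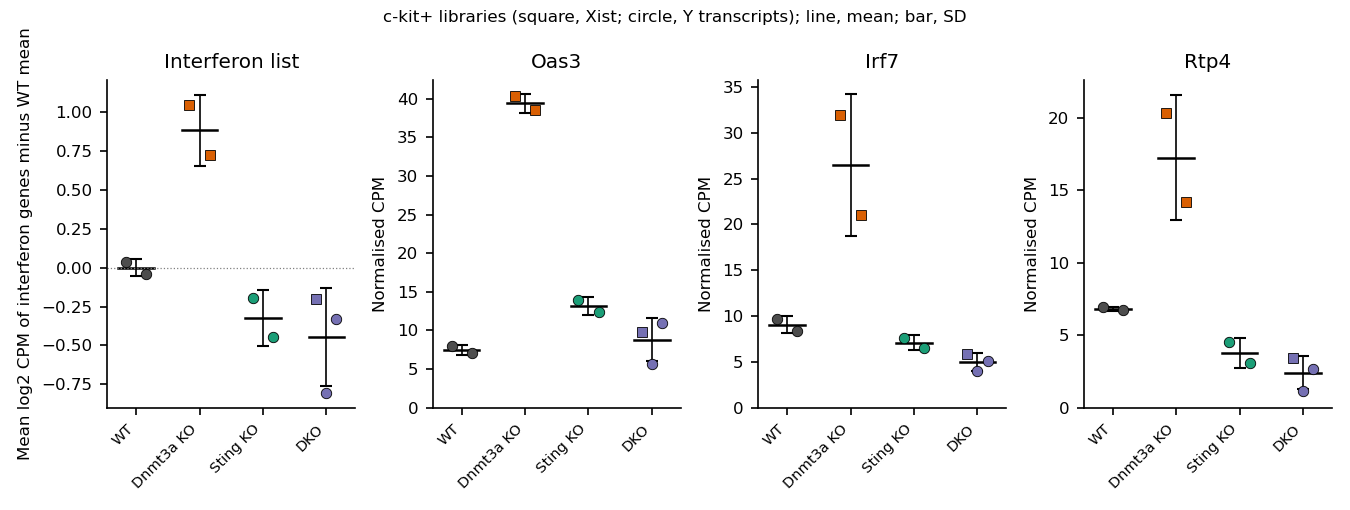
Mean log2 level of the 44 interferon genes over the WT mean in each c-kit+ library, 1 point per library, with group means and SD. The Dnmt3a KO libraries lie at 1.05 and 0.72, and the Sting KO and DKO libraries between -0.80 and -0.19.

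DKO against Sting KO asks what loss of Dnmt3a changes without Sting. Dnmt3a was at 47.6 ± 4.96 CPM in DKO (n = 3) and 88.1 ± 13.7 CPM in Sting KO (n = 2; log2 -0.89, SE 0.117, adjusted p = 0.0892, edgeR), and Tmem173 had a log2 fold change of 0.11 (adjusted p = 0.752). The interferon list did not pass (median -0.09, adjusted p = 0.703, camera), with none of its 44 genes called, also when adjusted over the list alone. MHC class I shifted down, with 1 of 17 genes higher and 9 lower adjusted over the list alone (adjusted p = 5.35e-05, camera; adjusted p = 0.541 with an estimated correlation). The megakaryocytic list shifted up with 17 of 17 fold changes positive (7.13e-05; adjusted p = 0.791 with an estimated correlation), as did germline genes (1 of 4 adjusted over the list alone, 0.0372; 0.541). G1/S (0.0226; 0.961 estimated) and stromal and endothelial genes (0.0442; 0.966) shifted down. The other 16 lists had adjusted p from 0.101 to 0.967, and median, mean and test differed in sign for nucleic acid sensing, NF-kB, stem cell, T and NK cell, imprinted and handling stress genes. By edgeR 0 of 16026 genes passed, with 1854 at an unadjusted p under 0.05, against 111 by DESeq2 and 0 by voom. Left-out libraries gave for genes changed in c-kit+ DKO against Sting KO 2 without DKO 2, 16 without DKO 3, 9 without Sting KO 1 and 6 without Sting KO 2.

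DKO against WT gives the combined change. Ifit3 (19: 34583119 to 34588982), an interferon-induced protein, was at 0.467 ± 0.141 CPM in DKO (n = 3) and 2.49 ± 0.471 CPM in WT (n = 2; log2 -2.40, SE 0.421, adjusted p = 0.0332, edgeR), and Lgals3bp fell by 0.66 (SE 0.121, adjusted p = 0.0383). Of the 44 interferon genes 2 fell, with 2 higher and 7 lower when adjusted over the list alone (median -0.27, adjusted p = 0.00670, camera; adjusted p = 0.692 with an estimated correlation). Ikbke (1: 131254600 to 131279601), a kinase that activates interferon regulatory factors, rose from 53.3 ± 0.848 to 91.7 ± 10.5 CPM (adjusted p = 0.0271), and H2-Q7 (17: 35439140 to 35443773), an MHC class I gene with close copies and so uncertain, fell from 23.9 ± 0.127 to 13.5 ± 2.82 CPM (adjusted p = 0.0477). Cd5l (3: 87357881 to 87371074), a secreted protein of tissue macrophages, fell from 132 ± 3.20 to 13.5 ± 10.8 CPM (log2 -3.28, SE 0.614, adjusted p = 0.0402). Siglec1 (2: 131067801 to 131086778), a sialic acid receptor, fell by 3.04 (adjusted p = 0.0270), and Spic (10: 88675269 to 88683023), a transcription factor of macrophages that recycle iron, by 2.65 (adjusted p = 0.0425). Hmox1 fell by 2.97, Adgre1 by 1.45, Cd68 by 1.13, Rims3 by 2.78 and Col14a1 (15: 55307644 to 55520803), a collagen, by 3.62 on the log2 scale (adjusted p from 0.00225 to 0.0364). Car1 (3: 14766214 to 14808365), the carbonic anhydrase of red cells, fell from 841 ± 19.9 to 435 ± 102 CPM (adjusted p = 0.0355). Mgst2 (3: 51636912 to 51682675), a glutathione transferase of leukotriene synthesis, rose by 2.05, Sytl1 (4: 133253090 to 133263087), a vesicle traffic protein, by 1.40 and the transporter gene Abca13 (11: 9191942 to 9684871) by 1.40. Ankrd22 (19: 34122549 to 34166041) rose by 1.59 and the imprinted gene Impact (18: 12954690 to 12992950) by 0.51, and adjusted p of these 5 genes ranged from 0.0133 to 0.0425. Pnp2, Chil3, Rps4l and Apobec3 rose by 5.29, 3.97, 1.99 and 1.40 (adjusted p from 0.000253 to 0.0104). LOC108169013, without a position in the gene table, was at 449 ± 18.5 CPM in WT, 298 ± 421 CPM in Sting KO, 0.0356 ± 0.0503 CPM in Dnmt3a KO and 0.0180 ± 0.0312 CPM in DKO.

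The granulocytic list shifted up in DKO against WT with all 16 fold changes positive and 11 genes higher adjusted over the list alone (adjusted p = 1.89e-06, camera; adjusted p = 0.577 with an estimated correlation), as did G2/M (0 of 17 called, 0.000251; 0.577 estimated) and megakaryocytic genes (0 of 17, 0.0289; 0.692). MHC class I (1 of 17 lower, 9 adjusted over the list alone, 0.000385; 0.577) and stromal and endothelial genes (0 of 11, 0.00268; 0.577) shifted down. B cell (0.00742), erythroid (1 of 22 lower, also adjusted over the list alone, 0.0275) and monocytic genes (3 of 15 lower, with 2 higher and 5 lower adjusted over the list alone, 0.0353) shifted down too, with adjusted p = 0.692 with an estimated correlation. The other 13 lists had adjusted p from 0.0963 to 0.796, with signs that differed for NF-kB, imprinted, TE silencing and handling stress genes. By edgeR 202 genes changed, 85 higher and 117 lower, against 890 by DESeq2 (548 higher, 342 lower) and 227 by voom. Tmem173 fell by 2.46 (adjusted p = 1.6e-05, edgeR) and Dnmt3a by 0.82 on the log2 scale (SE 0.117, adjusted p = 0.0154). For genes changed in c-kit+ DKO against WT the count was 10 without WT 1, 19 without WT 2, 77 without DKO 1, 946 without DKO 3, 86 without Dnmt3a KO 1, 84 without Dnmt3a KO 2 and 73 with the term for sex. Dnmt3a in c-kit+ DKO against WT lost its call without WT 1 (log2 -0.74) or WT 2 (-0.91).

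The interaction asks whether loss of Dnmt3a acts differently without Sting, as the log2 change from Sting KO to DKO minus that from WT to Dnmt3a KO. Oas3 had an interaction of -2.97 (SE 0.342, adjusted p = 0.0136, edgeR), with means of 7.48 CPM in WT, 39.4 CPM in Dnmt3a KO, 13.1 ± 1.13 CPM in Sting KO and 8.79 CPM in DKO. Of the 44 interferon genes 43 had negative interactions, 1 passed over all genes and 21 passed adjusted over the list alone (median -0.76, adjusted p = 2.08e-20, camera; adjusted p = 0.535 with an estimated correlation). Among positive interactions, Prg2 (1.97, SE 0.225, adjusted p = 0.0136) had 2810, 1011, 1205 and 1700 CPM in WT, Dnmt3a KO, Sting KO and DKO. The eosinophil ribonuclease genes Ear2 (14: 44102654 to 44103531) and Ear1 (14: 43818765 to 43819639), near-identical copies and so uncertain, had 2.30 and 2.27. Alox15 (11: 70344147 to 70390538), a lipoxygenase of eosinophils, had 3.03 and Gpr137b 4.85. Vcam1 (3: 116110020 to 116129688), an adhesion molecule, had 1.43, Slc40a1 (1: 45908070 to 45926532), the iron exporter ferroportin, 1.35 and Trf (9: 103208876 to 103230286), transferrin, 1.48, with adjusted p from 0.00937 to 0.0266. Negative interactions were found for Pnp2 (-5.11), its neighbour and copy Pnp (14: 50944303 to 50953412; -1.02), Ppp1r3e (14: 54875597 to 54877538), a regulator of glycogen synthesis (-2.63), Hist1h4i (-2.18), Ero1lb (-2.09), Apobec3 (-2.07) and Slfn9 (11: 82974316 to 82991830), a Schlafen family gene (-1.17), with adjusted p from 0.00210 to 0.0385. Pnp was at 153 ± 20.6 CPM in WT and 294 ± 8.74, 313 ± 23.4 and 297 ± 5.77 CPM in Dnmt3a KO, Sting KO and DKO, so that its interaction reflects a level in WT that differs from that of all mutant groups. Pnp2, Ppp1r3e, Apobec3, Slfn9, Ear2, Vcam1, Slc40a1 and Trf were likewise called against WT in all 3 mutant groups and not in DKO against Sting KO, where their log2 fold changes ranged from -0.34 to 0.64.

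Monocytic genes (6 of 15 higher adjusted over the list alone, adjusted p = 0.000316, camera; 0.572 estimated) and basophil, mast cell and eosinophil genes (1 of 9 over all genes, 3 adjusted over the list alone, 0.00123; 0.572) had positive interactions as lists. So did B cell (0.0146; 0.633), stromal and endothelial (1 of 11 adjusted over the list alone, 0.0146; 0.629), germline (0.0203; 0.535), handling stress (0.0203; 0.633), lymphoid priming (0.0352; 0.633) and NF-kB and inflammatory genes (0.0419; 0.633), where each latter value is the adjusted p with an estimated correlation. Monocytic and B cell lists were below WT in every mutant group and did not pass in DKO against Sting KO. Their interactions may reflect the WT level. MHC class I had a negative interaction (2 of 17 lower adjusted over the list alone, 0.00787, or 0.572 estimated). The other 12 lists had adjusted p from 0.0537 to 0.925, and signs differed for T and NK cell and methylation genes. By edgeR 24 of 16026 genes had an interaction, 12 positive and 12 negative, against 198 by DESeq2 and 59 by voom. Dnmt3a (-0.08, adjusted p = 0.980) and Tmem173 (0.51, adjusted p = 0.465) did not pass. The number of genes with a Dnmt3a by Sting interaction in c-kit+ was 4 without Dnmt3a KO 1, 2 without Dnmt3a KO 2, 41 without DKO 1, 128 without DKO 2, 15 without Sting KO 1, 13 without Sting KO 2, 5 without WT 1, 7 without WT 2 and 5 with the term for sex.

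**Figure D3:**
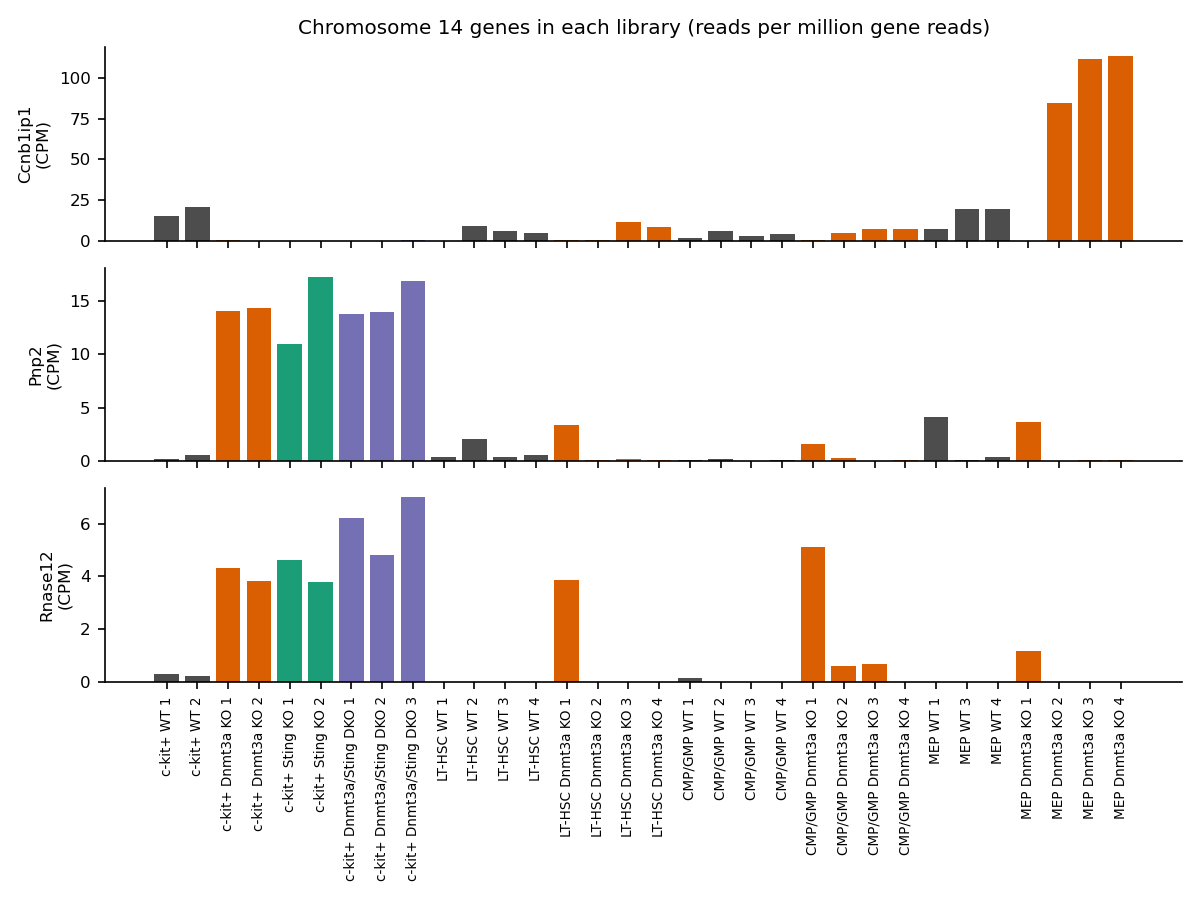
Levels in CPM of Ccnb1ip1, Pnp2 and Rnase12, genes of chromosome 14, in every library with gene counts, 1 bar per library. Among c-kit+ libraries Ccnb1ip1 is at 15.3 and 20.4 CPM in WT, and Pnp2 is at 0.192 and 0.550 CPM in WT and up to 17.3 CPM in the mutant libraries, all of which lie above WT.

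Comparisons against the same libraries share their chance values, so they were set beside 20 simulated draws of unchanged groups. Across 16026 genes, which are not independent replicates, the fold changes of Dnmt3a KO and Sting KO against WT had r = 0.527, against a simulated mean of 0.494 and highest of 0.528. Their covariance was 0.313 against a simulated 0.118, a difference of 0.195. They shared 49 called genes in the same direction, where independent lists give 0.340 and the simulation at most 1. Dnmt3a KO and DKO against WT had r = 0.700 (simulated 0.546), 60 shared calls (0.567 for independent lists) and a covariance difference of 0.284. Sting KO and DKO against WT had r = 0.679 (simulated 0.548), 86 shared calls (0.837) and a difference of 0.217. A split of the 2 WT libraries would leave 1 on each side and was not made, so part of the excess may come from the shared controls. Of the 25 genes lower in DKO than in Dnmt3a KO, 13 were among those higher in Dnmt3a KO than in WT (0.0764 for independent lists), with r = -0.58 against a simulated mean of -0.56 and a covariance difference of -0.168. Dnmt3a KO against WT and DKO against Sting KO share no library, and had r = 0.188 (simulated -0.00027). The correlation of the Dnmt3a loss effect with and without Sting across genes was 0.447 among genes at a mean CPM of 20 or more. Of the 91 genes called in Dnmt3a KO against WT, 43 had the same direction in DKO against Sting KO, with a median of -0.01 in their own direction against 1.31.

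In LT-HSC the comparison of Dnmt3a KO with WT asks what loss of Dnmt3a changes in stem cells, with the library labelled KO 3 at a WT level of Dnmt3a. Dnmt3a was at 71.0 ± 33.1 CPM in KO and 131.6 ± 75.3 CPM in WT (n = 4 each; log2 -0.89, SE 0.454, adjusted p = 1, edgeR), and Tmem173 had a log2 fold change of -0.26 (adjusted p = 1). Abundant interferon genes had similar means, with Ly6e, a membrane protein, at 1202 ± 195 and 1304 ± 91.6 CPM and Ifitm3, a restriction factor, at 804 ± 226 and 905 ± 233 CPM. The interferon list did not pass (0 of 40 genes, adjusted p = 0.842, camera), and its median of -0.05 and mean of 0.03 differ in sign. G1/S genes shifted up as a list (adjusted p = 0.0202, camera; adjusted p = 0.950 with an estimated correlation). Of them, 12 of 14 had positive fold changes and none passed, among them the replication genes Mcm3 (398 ± 83.9 against 324 ± 105 CPM) and Mcm6 (409 ± 175 against 311 ± 66.6 CPM). The other 18 lists had adjusted p from 0.517 to 0.954, with 1 lymphoid priming gene lower and 1 monocytic gene higher adjusted over the list alone. Signs of median, mean and test differed for nucleic acid sensing, granulocytic, erythroid and megakaryocytic genes too. By edgeR 0 of 12800 genes changed, with 151 at an unadjusted p under 0.05, against 7 by DESeq2 and 0 by voom. KO 2 and WT 1 stood apart from their groups, with rank correlations of 0.632 to 0.655 (KO 2) and 0.634 to 0.688 (WT 1) to the other libraries of the group, where the other pairs had 0.854 to 0.880 (KO) and 0.850 to 0.867 (WT). In these 2 libraries 11.7% and 12.1% of mid-level genes were missing, against 3.54% to 5.66% in the others, and both had Y transcripts. Without both, an alternative chosen after seeing the data, the number of genes changed by Dnmt3a KO in LT-HSC was 0 by edgeR, with 412 at an unadjusted p under 0.05.

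In CMP/GMP the same comparison concerns myeloid progenitors. Dnmt3a was lower in every KO library, at 24.9 ± 9.51 against 63.6 ± 13.5 CPM (n = 4 each; log2 -1.36, SE 0.296, adjusted p = 0.298, edgeR). That difference did not pass over all genes, and Tmem173 had a log2 fold change of 0.25 (adjusted p = 0.779). Megakaryocytic genes shifted up as a list (median 0.80, 5 of 16 higher adjusted over the list alone, adjusted p = 8.76e-05, camera; adjusted p = 0.693 with an estimated correlation). Pf4, a platelet chemokine, was at 488 ± 139 and 192 ± 50.6 CPM (log2 1.35, SE 0.250, adjusted p = 0.285). Granulocytic genes shifted up with 11 of 11 fold changes positive and 1 higher adjusted over the list alone (0.00479; adjusted p = 0.693 with an estimated correlation), with Mpo, myeloperoxidase, at 12190 ± 3864 and 9462 ± 7749 CPM. Cxcl12, a chemokine of stromal cells, was at 0.723 ± 1.15 and 52.96 ± 36.9 CPM (adjusted p = 0.338). The interferon list did not pass (0 of 40 genes, median -0.0015, adjusted p = 0.813). The other 18 lists had adjusted p from 0.126 to 0.844, with 2 stem cell genes, 1 NF-kB gene higher and 2 stromal and 1 methylation gene lower adjusted over the list alone, and signs that differed for lymphoid priming, erythroid and B cell genes. By edgeR 0 of 13205 genes changed, with 1196 at an unadjusted p under 0.05, against 158 by DESeq2 and 475 by voom. WT 2 and WT 4 were near-identical in their counts, and the number of genes changed by Dnmt3a KO in CMP/GMP was 1 without KO 3 and 12 without WT 3.

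In MEP the comparison concerns progenitors of red cells and platelets, with 4 KO and 3 WT libraries and with KO 2 at a WT level of Dnmt3a. Dnmt3a was at 13.7 ± 18.9 CPM in KO and 35.2 ± 10.5 CPM in WT (log2 -1.38, SE 1.07, adjusted p = 0.575, edgeR), and Tmem173 at 14.6 ± 20.4 and 4.19 ± 3.25 CPM (adjusted p = 0.583). Pf4 was at 259 ± 89.9 and 50.3 ± 15.6 CPM (log2 2.36, SE 0.403, adjusted p = 0.315) and Car1 at 3342 ± 1020 and 7507 ± 1000 CPM (log2 -1.17, SE 0.315, adjusted p = 0.315). The protease gene Mcpt8, of basophils and mast cells, was at 24.3 ± 21.9 CPM in KO and 0.139 ± 0.242 CPM in WT (adjusted p = 0.315). None of the 20 lists tested passed in camera, with adjusted p from 0.0991 for TE silencing and for basophil, mast cell and eosinophil genes to 0.877 for interferon genes, and no gene of the 36 in the interferon list changed. Adjusted over the list alone, 2 stem cell, 2 basophil, mast cell and eosinophil, 2 handling stress, 1 monocytic and 1 megakaryocytic gene were higher and 1 MHC class I gene was lower. Median, mean and test differed in sign for nucleic acid sensing, NF-kB, T and NK cell and stromal genes. By edgeR 0 of 12323 genes changed, with 1607 at an unadjusted p under 0.05, against 539 by DESeq2 and 7800 by voom. In simulated MEP data, drawn without near-identical libraries, DESeq2 made 60 false calls, edgeR 3 and voom 0. KO 3 and KO 4 were near-identical in their counts (rank correlation 0.992), while KO 1 and KO 2 stood apart from the other KO libraries and from each other (0.554 to 0.711, against 0.918 to 0.940 in WT). The number of genes changed by Dnmt3a KO in MEP was 2882 without KO 1, where the near-identical KO 3 and KO 4 make up most of the KO group and narrow its spread. Genes called in c-kit+ cells, taken as lists in the sorted populations, a test chosen after seeing the data, did not pass in any of the 3 populations (adjusted p from 0.596 to 0.955, camera).

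Whether the change under Dnmt3a loss differs between LT-HSC, CMP/GMP and MEP was tested as an interaction, and 3 of 16136 genes passed. None of the 3 kept its call with the replicate number, or genotype and number, as a block. The test takes libraries of the same genotype and number in different populations as independent, although in 7 of 8 such sets the libraries had a single kind of sex transcripts. Erdr1, a gene near the end of the sex chromosomes, was read in all or in no libraries of each such set. Pias3 (3: 96696361 to 96706070), an inhibitor of STAT3 signalling, was at 37.6 ± 7.99 CPM in KO and 18.3 ± 2.38 CPM in WT in LT-HSC (log2 1.03), at 22.03 ± 14.4 and 23.7 ± 6.34 CPM in CMP/GMP (-0.10) and at 1.45 ± 0.576 and 23.3 ± 5.02 CPM in MEP (-3.99; interaction adjusted p = 0.0364, edgeR). Tmem50b (16: 91574508 to 91597680), a membrane protein, was at 56.1 ± 17.1 and 48.2 ± 17.7 CPM in LT-HSC, 59.7 ± 3.53 and 44.0 ± 27.9 CPM in CMP/GMP and 0.221 ± 0.261 and 3.61 ± 0.778 CPM in MEP (adjusted p = 0.0419). Prss50 (9: 110857964 to 110864629), a serine protease, had 0 reads in all 4 LT-HSC KO libraries, which allows up to 0.0845 to 0.177 CPM, and 2, 932, 1370 and 563 reads in WT. It was at 14.5 ± 9.92 and 7.15 ± 5.13 CPM in CMP/GMP and 100 ± 49.8 and 239 ± 119 CPM in MEP (adjusted p = 0.0419). These 3 genes were named after their values were seen. DESeq2 called 111 genes and voom 4106, and 1929 had an unadjusted p under 0.05. The count of genes with a population by Dnmt3a interaction was 844 without MEP KO 1, with the near-identical MEP KO 3 and KO 4 left in. This count was 6 without MEP KO 2 and 1 without CMP/GMP KO 3, CMP/GMP KO 4 or LT-HSC KO 2. It was 0 without CMP/GMP KO 2, WT 1, WT 2 or WT 4, without LT-HSC KO 1, KO 3, KO 4, WT 2, WT 3 or WT 4, and without MEP KO 3, KO 4, WT 1, WT 3 or WT 4.

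TE subfamilies were compared because Dnmt3a methylates and silences repeats. In c-kit+ cells, TE levels are normalised reads in CPM of gene reads. MTB_Mm-int, an internal part of a MaLR element, was at 9.85 ± 0.699 in Dnmt3a KO and 4.17 ± 0.254 in WT (n = 2 each; log2 1.24, adjusted p = 0.00331, edgeR). L1M4a1, an old LINE-1, was at 5.17 ± 0.842 and 2.38 ± 0.0387 (1.11, adjusted p = 0.00936) and IAPEY4_I-int, of an intracisternal A particle, at 85.1 ± 7.91 and 190 ± 7.39 (-1.16, adjusted p = 0.00936). In Sting KO against WT, RLTR4_MM-int, of a murine leukaemia virus, rose from 207 ± 0.955 to 666 ± 148 (log2 1.69, adjusted p = 0.00268), and IAPEY4_I-int fell by 1.10 (adjusted p = 0.0199). In DKO against Dnmt3a KO, ERVB2_1-I_MM-int fell from 2.51 ± 0.334 to 0.369 ± 0.151 (log2 -2.74, adjusted p = 0.000525). In DKO against Sting KO, RLTR4_MM-int, RLTR4_Mm and MuLV-int fell, with log2 fold changes of -1.54, -1.19 and -1.08 (adjusted p = 0.00116, 0.00116 and 0.0102). In DKO against WT, Lx, a LINE-1 family, rose (296 ± 46.2 in DKO, n = 3, and 148 ± 16.4 in WT, n = 2; log2 1.01, adjusted p = 0.0179), and MuLV-int fell (-0.98, adjusted p = 0.0402). Interactions were found for RLTR4_MM-int (-2.60, adjusted p = 0.000421), MTB_Mm-int (-1.56, 0.00354), IAPEY4_I-int (1.65, 0.00424) and RLTR4_Mm (-1.44, 0.00697). These families have many near-identical copies, so how their reads were divided is uncertain. The number of TE subfamilies changed in c-kit+ Dnmt3a KO against WT, 3 of 916, was 0 with TE library sizes, 0 without WT 1 or WT 2, 12 without Sting KO 1 or Sting KO 2, 7 without DKO 1, 19 without DKO 2 and 14 without DKO 3. The number of TE subfamilies changed in c-kit+ Sting KO against WT, 2, was 0 with TE library sizes, 0 without WT 1 or WT 2, 4 without Dnmt3a KO 1, Dnmt3a KO 2 or DKO 1 and 5 without DKO 2. That of TE subfamilies changed in c-kit+ DKO against Dnmt3a KO, 1, was 2 without Dnmt3a KO 2, DKO 1, Sting KO 1 or Sting KO 2 and 5 without DKO 3.

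In the sorted populations edgeR called 0 TE subfamilies, with 9 of 904 at an unadjusted p under 0.05 in LT-HSC, 48 of 944 in ST-HSC, 61 of 893 in CMP/GMP and 140 of 857 in MEP, while DESeq2 called 6 in CMP/GMP, 24 in MEP and 0 in LT-HSC and ST-HSC. The number of TE subfamilies changed by Dnmt3a KO in MEP was 364 without KO 1, which leaves in the near-identical KO 3 and KO 4, and 1 without KO 3. TE reads per 100 gene reads were 8.46 ± 4.24 in MEP KO (n = 4) and 3.97 ± 1.01 in MEP WT (n = 3; two-sided exact permutation p = 0.143, where the smallest possible is 0.0286). By library, KO 1 had 2.22, below WT (2.87 to 4.85), and KO 2 and the near-identical KO 3 and KO 4 had 11.4, 10.8 and 9.41. More mid-level genes were missing in KO 2, KO 3 and KO 4 (10.4%, 7.55% and 8.01%) than in KO 1 (3.20%) and WT (1.84% to 2.93%). TE reads per 100 gene reads were 7.39 ± 3.76 and 7.21 ± 3.59 in LT-HSC (exact p = 1) and 3.21 ± 0.634 and 3.73 ± 0.269 in CMP/GMP (exact p = 0.200). In c-kit+ cells they were 3.29 ± 0.253 in WT, 3.63 ± 0.141 in Dnmt3a KO, 3.30 ± 0.0830 in Sting KO and 3.47 ± 0.136 in DKO, where the exact test cannot go below p = 0.333 for 2 libraries against 2 or 0.1 for 3 against 2. All adjusted p-values of the 8 comparisons were 0.64 or more (exact permutation tests).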

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

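The tests of the near-identical libraries, of loss of Dnmt3a and of a chromosome segment as sources of the WT difference, of sex, monocytes and macrophages in DKO against Dnmt3a KO, and of sex without LT-HSC KO 2 and WT 1 were chosen only after the result was seen. The gene, list and TE results of the c-kit+ interaction were picked for a closer look because the change under Dnmt3a loss differed with and without Sting. They comprise 24 genes, 10 lists, with the interferon list at adjusted p = 2.08e-20, and 4 TE subfamilies. Pias3 (adjusted p = 0.0364), Prss50 (0.0419) and Tmem50b (0.0419), by edgeR, were picked because their change differed between populations. Single values per library, such as read totals and TE reads per 100 gene reads, set no library apart in the 32 groups and measures tested, where chance picks about 1 in 20. By rank correlation LT-HSC KO 2 (0.632 to 0.655 with its group) and WT 1 (0.634 to 0.688) did stand apart from the other pairs (0.850 to 0.880), with 12.3 and 12.4 TE reads per 100 gene reads against 3.81 to 8.16 in the other LT-HSC libraries. MEP Dnmt3a KO 1 (0.554 to 0.621) and KO 2 (0.554 to 0.711) had correlations with their group as low, where the MEP WT pairs had 0.918 to 0.940.

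Interferon genes were high in c-kit+ Dnmt3a KO (median log2 fold change against WT 0.82) and low in DKO (-1.12 against Dnmt3a KO). Sex as the source of the difference between DKO and Dnmt3a KO is argued against only by the Xist library DKO 1, which lay below WT (-0.20). The median of -0.99 with the sex signal as a term rests on the same library, since only DKO held both Xist and Y libraries. Fewer monocytes or macrophages in DKO stay open, since the monocytic list (median 0.0275) went both ways with 6 of 15 genes lower, and 13 macrophage genes outside the fixed lists had a median of -0.82 against Dnmt3a KO (12 lower, 0 passed singly), although their means were highest in WT. Sex stays open too for Dnmt3a KO against WT, where every Dnmt3a KO library had Xist and every WT library Y transcripts, and where a median of 0.54 was left with the sex term. In libraries of the same genotype, the interferon median of Xist against Y libraries was 0.48 in LT-HSC (adjusted p = 0.0314, camera; 0.599 with an estimated correlation), -0.09 in CMP/GMP (0.256) and -0.12 in MEP (0.362), but in LT-HSC KO 2 and WT 1 are among the Y libraries, and without them it was 0.07 (p = 0.722, camera), so these values do not decide between sex and loss of Dnmt3a.

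Of the genes called in c-kit+ cells, 44 differed between WT and each of the 3 mutant groups, 19 higher and 25 lower in the mutants. Loss of Dnmt3a as the source in all 3 groups is argued against by Sting KO, where Dnmt3a itself had a log2 fold change of 0.0671 (SE 0.129, adjusted p = 0.884, edgeR) against WT. A strain variant or chromosome segment remains a candidate explanation, as 14 of the 44 lay on chromosome 14, against 541 of 15495 tested genes. The smallest adjusted p over chromosomes was 3.26e-09 (one-sided Fisher's exact test), though neighbouring genes are not independent. Linkage to Dnmt3a or Tmem173, on other chromosomes, cannot explain these 14. The stretch from 50789249 to 54877538 held 9 of them, with Ccnb1ip1, Pnp2, Psmb5 and Ppp1r3e, among 56 tested genes, of which 43 were called in none of the 3 comparisons. For genes that fell, fewer macrophages in the mutant preparations may account for part, since 13 macrophage genes outside the fixed lists had medians of -1.65, -2.68 and -2.45 in Dnmt3a KO, Sting KO and DKO (0, 0 and 7 of the genes passed singly), with Axl at 202 CPM in WT and 57.7, 30.9 and 36.8 CPM in the mutants, although selection for c-kit should remove macrophages.

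Nearly identical pairs were found, as CMP/GMP WT 2 and WT 4 had a rank correlation of 0.984 (other pairs of the population up to 0.943), MEP Dnmt3a KO 3 and KO 4 of 0.992 (up to 0.940), and ST-HSC Dnmt3a KO 3 and KO 4 a TE correlation of 0.996 (up to 0.942). A single library deposited under both labels is argued against by a mean chi-square per gene of at least 24.3 between the counts of the CMP/GMP and MEP pairs, where resampled reads give about 1. Separate libraries from one amplified cDNA stay a candidate. Mid-level genes missing in 1 library of the pair were missing in both in 68.8% (CMP/GMP) and 79.8% (MEP) of cases. This was at least 2.73 times the highest other pair, though Erdr1 had 20 reads in CMP/GMP WT 2 and 0 in WT 4. The c-kit+ pairs were all close (0.981 to 0.996), closest in Dnmt3a KO 1 and KO 2 with a mean chi-square of 7.04 against 22.7 or more in the others, and since at most 0.109% of mid-level genes were missing in a c-kit+ library, shared absence could not test a shared cDNA there. No biological explanation was tested, and replicates of these groups, c-kit+ Dnmt3a KO included, may then be fewer than labelled.

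Other splits of the sorted libraries into groups of the same sizes were tested against the real one. For genes in LT-HSC, CMP/GMP and MEP, and for TE subfamilies in these and in ST-HSC, the real count was 0, which 35 of 35 splits must reach, so the comparison decides nothing about chance. The highest other counts were 4, 54 and 3688 for genes in LT-HSC, CMP/GMP and MEP, and 246, 3, 43 and 432 for TE subfamilies in LT-HSC, ST-HSC, CMP/GMP and MEP. The interferon list had an adjusted p as small as the real 0.842, 0.813 and 0.877 in 33 splits of LT-HSC, 24 of CMP/GMP and 30 of MEP, with 0.0215, 0.0172 and 0.0266 as the most extreme others. As many lists as the real 1 in LT-HSC and 2 in CMP/GMP passed in 26 and 19 splits, with highest others of 7 and 7, while the real 0 lists of MEP (highest other 9) again decide nothing. For the difference between populations, 16 of 100 drawn splits gave as many genes as the real 3, and the highest other gave 2735. Chance could not be excluded for the interferon list in the 3 populations, for the list counts of LT-HSC and CMP/GMP and for the difference between populations. In the MEP split with 3688 genes, only KO 1 leaves its genotype to join the 3 WT libraries, and the near-identical KO 3 and KO 4 stay together. That split therefore cannot tell the genotype from another structure of the samples. The LT-HSC split with 246 TE subfamilies put KO 1, KO 4, WT 2 and WT 3 against the rest. It mixes both genotypes evenly, so its calls point to a structure of the samples other than the genotype.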

How the results depend on the processing

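The term for sex, the tests without genes of chromosomes X and Y, the block of genotype and number, and the libraries summed or left out as pairs were chosen only after the result was seen. Depth limits differ, with 3.44 M gene reads in the smallest MEP library against 27.4 M in the smallest c-kit+ library, and groups of 2 rest on the spread shared by the fit. ST-HSC genes and its interferon list, and call overlaps between sorted populations, were not run. For counts, the interferon list, TE reads per 100 gene reads and the correlation of effects, 257 values under an alternative stayed on their side of the threshold, or within 1.5 times for counts, while 135 moved, 17 changed sign and 7 no longer passed. For single named genes, 919 values stayed on their side of the threshold, 357 no longer passed, 9 changed sign and 3 newly passed. The cause of these changes was not tested.

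For c-kit+ cells, 6 counts were taken: genes changed in c-kit+ Dnmt3a KO against WT, genes changed in c-kit+ Sting KO against WT, genes changed in c-kit+ DKO against Dnmt3a KO, genes changed in c-kit+ DKO against Sting KO, genes changed in c-kit+ DKO against WT and genes with a Dnmt3a by Sting interaction in c-kit+. In this order they were 91, 124, 25, 0, 202 and 24. DESeq2 gave 645, 449, 95, 111, 890 and 198, and no filter on low counts gave 1219, 735, 415, 408, 1359 and 446. With voom, Dnmt3a KO against WT, Sting KO against WT and the interaction had 924, 249 and 59. With only the 2 groups compared, Dnmt3a KO and Sting KO against WT had 1260 and 286, DKO against Dnmt3a KO 1 and DKO against WT 69. The sex term, which only the DKO libraries set in c-kit+ cells, gave 0 and 131 for Dnmt3a KO and Sting KO against WT, 1 for DKO against Dnmt3a KO, 73 for DKO against WT and 5 for the interaction. Without genes of X and Y they were 96, 137, 24, 0, 208 and 27. Leaving out each library in turn gave ranges of 6 to 289, 17 to 337, 1 to 74, 0 to 16, 10 to 946 and 2 to 128.

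In the sorted populations, genes changed by Dnmt3a KO in LT-HSC, genes changed by Dnmt3a KO in CMP/GMP and genes changed by Dnmt3a KO in MEP, all 0, became 7, 158 and 539 with DESeq2, and with voom CMP/GMP and MEP became 475 and 7800. In simulated data of these populations DESeq2 made 60, 45 and 60 false calls, edgeR 3, 6 and 3, and voom 0, 5 and 0. The simulated libraries were drawn independently, without near-identical pairs or libraries that stand apart. These values therefore cannot rank the methods on the real libraries. A joint fit gave 1 in LT-HSC and 12 in MEP. LT-HSC without KO 2 and WT 1, which had the fewest genes detected and the lowest rank correlations with their groups, and MEP without the near-identical KO 3 and KO 4, gave 0. With each library left out they ranged from 0 to 0, 0 to 12 and 0 to 2882. The 3 genes with a population by Dnmt3a interaction became 1 with RLE, 8 without the filter, 4106 with voom and 111 with DESeq2, and 0 to 844 with a library left out.

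Counts of TE subfamilies changed by Dnmt3a KO in LT-HSC, TE subfamilies changed by Dnmt3a KO in ST-HSC and TE subfamilies changed by Dnmt3a KO in CMP/GMP ranged from 0 to 0 and TE subfamilies changed by Dnmt3a KO in MEP from 0 to 364 with a library left out. DESeq2 gave 6 in CMP/GMP and 24 in MEP, no filter 2 in MEP, and the near-identical pair summed 1 in MEP. The 3 TE subfamilies changed in c-kit+ Dnmt3a KO against WT became 8 with DESeq2, 13 without the filter, 0 with TE library sizes and 0 to 19 with a library left out. The count of TE subfamilies changed in c-kit+ DKO against Dnmt3a KO, 1, became 2 with DESeq2, 3 without the filter and 1 to 5 with a library left out. The 2 TE subfamilies changed in c-kit+ Sting KO against WT became 1 with DESeq2, 0 with TE library sizes and 0 to 5 with a library left out.

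With a replicate block, genes changed in c-kit+ Dnmt3a KO against WT were 181, genes changed in c-kit+ Sting KO against WT 187, genes changed in c-kit+ DKO against Dnmt3a KO 11 and genes changed in c-kit+ DKO against WT 832, of which 84, 118, 10 and 194 were also called without it. TE subfamilies changed by Dnmt3a KO in MEP were 1, TE subfamilies changed in c-kit+ Dnmt3a KO against WT 14, TE subfamilies changed in c-kit+ DKO against Dnmt3a KO 5 and genes with a population by Dnmt3a interaction 0, as they were with a replicate block of genotype and number. The replicate block ended the calls of Dmpk, Oas1a, Tgtp2, LOC108169013, Trf, Slc40a1, Ppp1r3e, Ero1lb and Slfn9 in c-kit+ cells and those of Pias3, Prss50 and Tmem50b between populations, and no other call of a named gene. Within a population, the correlations do not show that the numbers pair libraries of different genotypes. Deviations of libraries with the same number correlated from -0.198 to 0.120 in LT-HSC, where 2 of 4 pairs were over 0.1, -0.0934 to 0.0781 in CMP/GMP, -0.0724 to 0.0932 in MEP and -0.0620 to 0.0663 in c-kit+ cells. Sex transcripts of the sorted libraries did match by number across genotypes. Numbers 1 and 2 had Y transcripts and numbers 3 and 4 Xist in both, except CMP/GMP WT 4, so pairing is not excluded. Between sorted populations, deviations of libraries with the same genotype and number correlated from -0.0619 to 0.230 (median 0.0538, 3 of 22 pairs over 0.1), and those with different numbers had a median of -0.0141. These correlations alone neither show nor exclude a shared animal. Erdr1, chosen after seeing the data, had reads in Dnmt3a KO 2 (48 in CMP/GMP, 10 in LT-HSC and 2 in MEP). It also had reads in WT 2 (20 in CMP/GMP and 11 in LT-HSC) and WT 3 (22 in CMP/GMP, 171 in LT-HSC and 29 in MEP). The other sorted libraries had 0 reads of Erdr1. Its presence thus followed genotype and number, which goes with shared animals, although sex transcripts of WT 4 differed between populations.

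The interferon list in c-kit+ Dnmt3a KO against WT had adjusted p = 0.673 with an estimated correlation, 0.0911 by fry, 9.2e-08 with the sex term and 6.27e-23 to 2.3e-13 with a library left out. The interferon list in c-kit+ DKO against Dnmt3a KO had 0.174 estimated, 1.58e-37 with the sex term and 2.71e-45 to 5.32e-30. The interferon list in c-kit+ Sting KO against WT had 0.679 estimated, 0.5255 by fry, 0.00961 with the sex term and 0.00675 to 0.488, and no longer passed without Sting KO 2 (0.488) or WT 1 (0.133). The interferon list under Dnmt3a KO in LT-HSC (0.238 to 0.895), the interferon list under Dnmt3a KO in CMP/GMP (0.541 to 0.986) and the interferon list under Dnmt3a KO in MEP (0.720 to 0.944) passed in none, and changed sign in LT-HSC without WT 1 (0.263), in CMP/GMP without KO 3 (0.541), WT 1 (0.986) or WT 4 (0.950), in MEP without KO 1 (0.720) or WT 1 (0.916) and in MEP by fry (0.8).

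With a library left out, differences in TE reads per 100 gene reads in LT-HSC Dnmt3a KO against WT ranged from -1.47 to 1.91, and were negative without KO 2 (-1.47), KO 3 (-0.0762), WT 2 (-0.836), WT 3 (-0.294) or WT 4 (-0.0557). They ranged from -0.808 to -0.306 for TE reads per 100 gene reads in CMP/GMP Dnmt3a KO against WT, 3.51 to 6.57 for TE reads per 100 gene reads in MEP Dnmt3a KO against WT, 0.159 to 0.517 for TE reads per 100 gene reads in c-kit+ Dnmt3a KO against WT, -0.253 to -0.0537 for TE reads per 100 gene reads in c-kit+ DKO against Dnmt3a KO, 0.0994 to 0.236 for TE reads per 100 gene reads in c-kit+ DKO against Sting KO and 0.00567 to 0.364 for TE reads per 100 gene reads in c-kit+ DKO against WT. TE reads per 100 gene reads in c-kit+ Sting KO against WT ranged from -0.164 to 0.193, were negative without Sting KO 2 (-0.0442) or WT 2 (-0.164), and turned for LINE (-0.00934) and SINE reads (-0.0503), as did DKO against Sting KO for LTR reads (-0.0410). The correlation of the Dnmt3a loss effect with and without Sting across genes was 0.447 at a mean CPM of 20 or more.

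Of 102 named values in c-kit+ cells 95 were calls, of which 57 and 60 were lost without Dnmt3a KO 1 and 2, 17, 3 and 6 without DKO 1, 2 and 3, 33 and 40 without Sting KO 1 and 2, and 69 and 63 without WT 1 and 2. All 95 were kept with DESeq2 and RLE. Signs of uncalled values turned for Tmem173 in LT-HSC Dnmt3a KO against WT without KO 2 (0.0762; range -0.55 to 0.0762), Dnmt3a in c-kit+ Sting KO against WT without Sting KO 2 (-0.11) or WT 2 (-0.015; range -0.11 to 0.22), Dnmt3a in c-kit+ DKO against Dnmt3a KO without Dnmt3a KO 1 (0.0053), DKO 1 (0.0750) or WT 1 (0.0020; range -0.0599 to 0.0750). So did Dnmt3a in c-kit+ interaction without DKO 1 (0.0080), Sting KO 2 (0.0923) or WT 2 (0.0056; range -0.23 to 0.0923). Dnmt3a passed in CMP/GMP with DESeq2 (-1.37) and in DKO against Sting KO with DESeq2 (-0.89) or without Sting KO 1 (-1.04).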

Other observations

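The values of chromosome 14, of Erdr1 and of the sex transcripts by number were chosen only after the result was seen, and the macrophage genes before. In the sorted cells, genes of chromosome 14 that separated c-kit+ WT from the mutants varied between libraries of the same genotype. Ccnb1ip1 was at 0.0578, 0.230 and 0 CPM in Dnmt3a KO 1 of LT-HSC, CMP/GMP and MEP, and Pnp2 was at 3.41, 1.58 and 3.71 CPM there. Rnase12, a ribonuclease with close relatives and so uncertain, was at 3.84, 5.12 and 1.15 CPM in the same libraries. MEP Dnmt3a KO 2, KO 3 and KO 4 had 84.9, 112 and 114 CPM of Ccnb1ip1. MEP WT 1 had 7.25 CPM of Ccnb1ip1 with 4.14 CPM of Pnp2, and LT-HSC WT 1 had 0 CPM and LT-HSC Dnmt3a KO 2 0.355 CPM of Ccnb1ip1. In c-kit+ cells Erdr1 had 201 and 118 reads in WT (6.43 and 2.95 CPM) and 0 in all mutant libraries. That allows up to 0.0822 to 0.109 CPM.

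The 13 macrophage genes outside the fixed lists had their highest mean in c-kit+ WT. C1qb, a complement subunit, was at 84.2 CPM in WT, 26.6 CPM in Dnmt3a KO, 13.9 CPM in Sting KO and 15.0 CPM in DKO (log2 -1.66, -2.60 and -2.48 against WT; adjusted p = 0.201, 0.0921 and 0.0494, edgeR). Timd4, a receptor for dying cells, was at 8.43, 1.06, 0.394 and 0.770 CPM and did not pass in any of the 3.

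Sex transcripts (Xist or Y) were of a single kind in 7 of 8 sets of sorted libraries with the same genotype and number. The exception was WT 4, with Xist in LT-HSC and MEP and Y transcripts in CMP/GMP (Xist at 0.803 CPM), and CMP/GMP WT 4 is the near-identical partner of CMP/GMP WT 2, which has Y transcripts.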
